A study of Homo sapiens with 5 samples.

How the data were processed

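The series holds 5 chromatin libraries of C42B cells, a castration-resistant human prostate cancer line derived from LNCaP. The cells were grown in charcoal-stripped serum, from which steroid hormones have been removed. There were 2 libraries immunoprecipitated with a pan HOXB13 antibody, 1 with an antibody to RNA polymerase II (RNA Pol II), 1 with control IgG and 1 of input chromatin that was not immunoprecipitated. Groups were taken from the sample titles. Nothing in the labels says that the 2 HOXB13 libraries came from separate cultures, so the spread between them may be technical.

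Per the submitters' processing notes, base calls came from CASAVA 1.4, reads were handled with Bowtie2 and MACS2, and the genome build was hg19 (GRCh37). Settings of these tools are not given in the sources used here. As a check of the build, the last peak of every chromosome was set against the chromosome lengths: 0 chromosomes had a peak past the end of hg19, and 15 had a peak past the end of hg38. All positions below are hg19, counted from 1.

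Each HOXB13 library and the RNA Pol II library had peaks called by the authors per library, once against IgG and once against input, which gave 6 deposited peak lists. The deposited lists give for each peak a fold enrichment, which is the peak caller's linear ratio of the ChIP signal to a background set from the control. How that background was set at each site is not given in the sources used here, so a fold need not measure the control at that site. They also give the −log10 of the p-value and of the q-value, as the authors' peak caller wrote them, and the distance of the summit from the peak start. The lists are marked as filtered, and the rule of that filter is not given in the sources used here. Peaks are numbered by strength: the highest number in a list lies between 64749 and 113719, and 21.5% to 44.6% of the numbers were kept. Among the first 5000 numbers of a list, 91.0% to 99.96% were kept. The smallest −log10 p in any deposited list was 2.03, so the lists reach down to weak peaks. Neither read totals nor read counts per peak were used here, so sequencing depth is unknown and the lengths of the lists are not compared as amounts of binding. Every fold below is the authors' value.

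Peaks of the 4 HOXB13 lists were merged where they overlapped or touched, and a HOXB13 region is a merged region with peaks of all 4 lists. An RNA Pol II region is a merged region with a peak of both RNA Pol II lists. Where a list had several peaks in a region, the largest fold was used. Peaks counted as shared at an overlap of at least 1 bp. The chance share came from circular shifts, in which all peaks of a list were moved along each chromosome by 1 random distance. There were 1000 shifts for the HOXB13 libraries with each other and for HOXB13 regions with RNA Pol II regions, 200 for other pairs and alternatives, and 100 for the number of regions. As a second, local estimate, each peak was moved by 50 to 500 kb in a random direction, 100 times. Shares carry 95% Wilson intervals, which cover counting error only. Peaks and regions are not replicates, so no p-value was computed across them. With 1 condition and 1 library for every antibody except HOXB13, no test between groups was possible.

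Lists called against the same control share that control's chance values, and this alone gives them peaks in common. Without read counts this share could not be simulated. Instead, the libraries were also compared with 1 called against IgG and the other against input, so that no control was shared. Since the controls are 1 library each, they could not be split. Along chromosomes, peaks were counted by summit in windows of 5 Mb with at least 20 peaks over all lists, and 1 peak was added before a log2 ratio of numbers was taken.

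The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with seed 7. The overlap code was tested on simulated lists placed beside the 29887 peaks of HOXB13 library 1 against IgG: planted shares of 10.0%, 40.0% and 80.0% came back as 10.4%, 40.1% and 79.9%. In 4 simulated lists with 500 planted common regions, 500 were found.

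The tests of the main comparisons, their first alternatives and the rule for named items were fixed before the data were examined. The comparison of peak numbers in windows and chromosomes, the ranking of regions into 5 groups, the clusters and most tests of the closing section were added later. The rule named the 10 HOXB13 regions with the largest fold against IgG, taken as the smaller of both libraries' values. No hg19 annotation or sequence was used here, so regions are given by position. For the same reason the planned shares at promoters, with HOX motifs and over gene lists, and the named genes, were not computed. Alternatives were a stricter −log10 q of at least 5, single controls, summits within 200 bp, reciprocal overlap of 50%, equal list lengths and each HOXB13 library left out. The alternatives added after the data were seen were different controls for the libraries, local shifts, regions in at least 3 lists, RNA Pol II lists taken singly, and named regions scored against input or without each library.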

Results

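Chromatin occupancy of HOXB13, a homeobox transcription factor of the prostate epithelium, was profiled by ChIP-seq in C42B cells, a castration-resistant prostate cancer line kept in charcoal-stripped serum. There were 2 HOXB13 libraries and 1 library each of RNA Pol II, control IgG and input. Against IgG, 29887 peaks were listed for HOXB13 library 1 and 25493 for library 2, and against input 31090 and 24405. RNA Pol II had 37716 peaks against IgG and 24435 against input. HOXB13 peaks were narrow, with a median width between 231 and 296 bp, and their median fold enrichment lay between 3.27 and 3.97. The highest fold in a HOXB13 list was 29.6, and in an RNA Pol II list 55.1. A −log10 q of at least 5 was reached by 14.6% to 27.4% of the peaks in the HOXB13 lists, and by 47.5% and 33.4% in the RNA Pol II lists. The q-value was under 5% for 74.5% of the peaks of library 1 against IgG, and for 91.3% to 96.5% in the other HOXB13 lists. Read totals were not used here, so the depth behind each list is unknown.

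The first comparison asked where HOXB13 occupied the genome of these cells in both libraries. A set of 2731 HOXB13 regions carried a peak of both libraries against both controls, with a median width of 406 bp. Shifting library 2 along the chromosomes left 8.06 such regions on average and 19 at most. Both libraries used the same controls, and the shifts break that link too, so these numbers speak to random placement only. In the 2731 regions the median fold against IgG was 5.13 in library 1 and 5.11 in library 2, and against input it was 5.48 and 5.62. The strongest summits of both libraries lay a median of 24 bp apart, and in 75% of regions within 45 bp. These regions were 3.32% of the 82336 merged regions, of which 61843 came from a single list. The number depended on the rule: with IgG lists alone there were 10471 regions, with input lists alone 8846, and with peaks of −log10 q of at least 5 there were 1488. With library 2 alone there were 5057 regions and with library 1 alone 6201, since fewer lists had to hold a peak.

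Strong HOXB13 peaks were found in both libraries, and most weak ones were in 1 library. Against IgG, 36.1% of the peaks of library 1 were found in library 2 and 41.6% of those of library 2 in library 1, where shifted positions gave 0.613% and 0.714%. Against input the shares were 28.8% and 36.4%, with 0.583% and 0.742% by chance. Each pair of shares is the same overlap read from either library, so it carries no SD, and with lists of equal length the mean of the pair was 39.5% against IgG and 32.8% against input. When the libraries were called against different controls, 11.5% to 15.8% of peaks were found in the other library, so the shared control may hold part of the overlap. A change of control within a library also left few peaks in common. Of a library's peaks, 19.9% to 20.8% were found in its own list against the other control. The fall is therefore not a measure of disagreement between the libraries alone. Among peaks with a −log10 q of at least 20, 99.5% to 99.8% were in the other library with the same control and 83.1% to 97.5% with the different one. Among peaks with a −log10 q under 2, the shares were 14.2% to 20.6% and 2.27% to 4.37%.

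**Figure D1:**
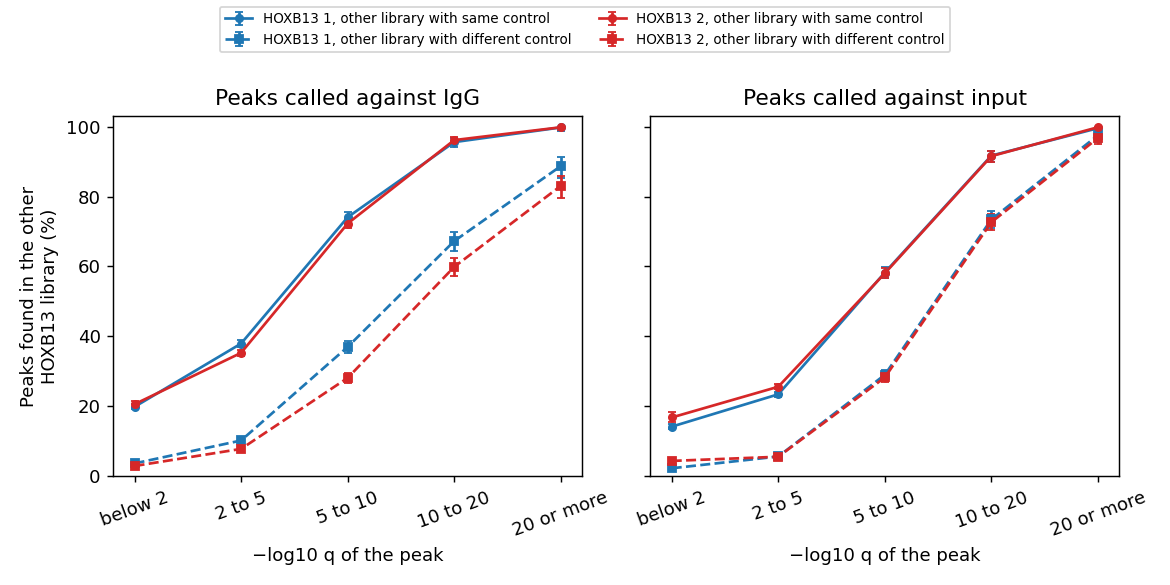
Share of HOXB13 peaks (%, y axis) that overlap a peak of the other HOXB13 library, by the −log10 q of the peak (x axis), for lists called against IgG (left) and input (right). Blue is library 1 and red library 2, solid lines use the other library's list with the same control and dashed lines its list with the different control, and bars are 95% Wilson intervals. Every line rises with peak strength, and the dashed lines lie below the solid ones in each class.

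Across the 2731 regions, the log2 fold against IgG of library 1 correlated with that of library 2 with Pearson r = 0.819 and Spearman rho = 0.785, and against input with r = 0.845 and rho = 0.828. Regions are not independent replicates, and both libraries shared the control. With library 1 against IgG and library 2 against input, r was 0.342 and the covariance 0.117, and with the controls exchanged 0.332 and 0.112. For comparison, the folds of a single library against IgG and against input correlated at 0.466 in library 1 and 0.441 in library 2, with covariances of 0.162 and 0.148. With the same control the covariance was 0.254 for IgG and 0.316 for input.

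The region with the largest HOXB13 fold against IgG was on chromosome 2, from 196521522 to 196522707, with a fold of 28.0 ± 0.327 (SD, n = 2 libraries). It was followed by a region on chromosome 14, from 95623568 to 95624204, at 24.8 ± 1.04, and by one on chromosome 11, from 64052957 to 64053668, at 23.3 ± 2.35. The region on chromosome 9 from 126030927 to 126031485 had 22.2 ± 2.41, and that on chromosome 6 from 34359452 to 34361218 had 20.3 ± 1.33. Both libraries were scored against the same control library, so each SD leaves out the error of the control. Ranking by the smaller value also favours regions where the libraries are alike. Against input the folds of these 5 regions were 5.60, 4.61, 8.32, 6.58 and 5.92, in the same order. All 5 overlapped an RNA Pol II peak called against IgG, and only the chromosome 2 region also overlapped one called against input.

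A second kind of named region was high against both controls. On chromosome 12, from 96841882 to 96842397, the fold was 19.3 ± 0.838 against IgG and 22.6 ± 0.138 against input, and no RNA Pol II peak was listed there. On chromosome 15, the region from 39846526 to 39846937 had 18.7 ± 0.0249 and 21.7 ± 1.21, and the region from 84599584 to 84600019 had 18.8 ± 1.05 and 19.5 ± 1.01. Both chromosome 15 regions overlapped RNA Pol II peaks of both lists. The last named regions lay on chromosome 17 from 55651146 to 55652092, with 19.4 ± 2.24 against IgG and 7.41 ± 0.694 against input, and on chromosome 8 from 36830676 to 36831121, with 18.0 ± 0.522 and 9.73 ± 0.154. Neither overlapped an RNA Pol II peak. Of the 10 named regions, 6 had a fold against IgG more than 2 times that against input, and 3 were also among the 10 with the largest fold against input. Choosing regions by their fold against IgG favours such an excess. Over all 2731 regions the median folds in libraries 1 and 2 were 5.13 and 5.11 against IgG, and 5.48 and 5.62 against input. No gene is given for these positions, since no annotation of this build was used here.

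**Figure D2:**
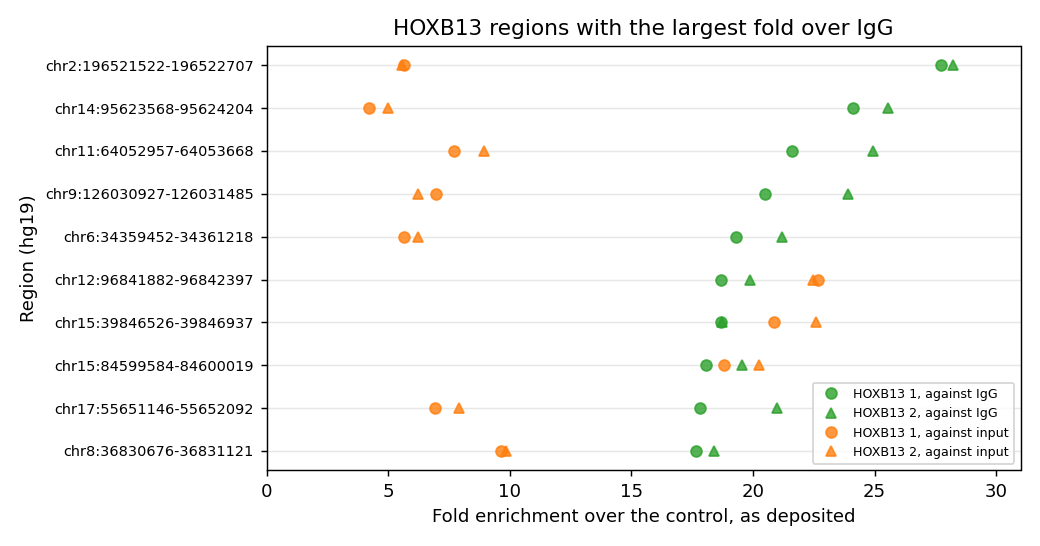
Fold enrichment (x axis, as deposited) of the 10 HOXB13 regions with the largest fold against IgG (y axis, hg19 positions). Circles are HOXB13 library 1 and triangles library 2, green against IgG and orange against input. The 5 uppermost regions lie near or above 20 against IgG and below 10 against input, and the chromosome 12 and 15 regions lie near 20 against both.

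Ranked by the fold against input, an order chosen after the values were seen, the leading region lay on chromosome 8 from 11031638 to 11032120, with 28.9 ± 1.03 against input and 12.7 ± 2.56 against IgG. A region on chromosome 10 from 33712032 to 33712410 had 22.9 ± 1.94 against input, and one on chromosome 3 from 159345307 to 159346154 had 22.2 ± 1.32. Of the 10 leading regions in this order, 3 overlapped an RNA Pol II peak called against IgG, compared with 7 of the 10 leading in the order by IgG. With the RNA Pol II list called against input the numbers were 4 and 3, and with RNA Pol II regions of both lists 3 and 3.

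The study called the HOXB13 and RNA Pol II libraries against IgG and against input, which asks how much a peak list owes to its control. Of the HOXB13 peaks called against IgG, 20.8% in library 1 and 19.9% in library 2 overlapped a peak of the same library called against input. In the reverse direction the shares were 19.98% and 20.7%. For RNA Pol II, 25.1% of the peaks called against IgG were also called against input, and 43.1% of those called against input were also called against IgG. Chance gave between 0.567% and 1.12% for these pairs. With peaks of −log10 q of at least 5 in both lists, 45.5% ± 7.03 (SD, n = 2) of HOXB13 peaks called against IgG and 38.0% ± 3.08 of those called against input were shared. Both HOXB13 libraries used the same control libraries, so each SD leaves out the error of the controls. At this q the RNA Pol II shares were 29.7% from IgG to input and 71.2% from input to IgG. With a reciprocal overlap of 50% the shares fell, to 18.8% from either list for HOXB13. For RNA Pol II they fell to 14.9% from IgG to input and 23.1% from input to IgG.

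The peaks called against each control were spread over the chromosomes in different proportions. Chromosome 3 held 7.52% and 7.47% of the HOXB13 peaks called against IgG in libraries 1 and 2, and 14.8% and 14.6% of those called against input. Chromosome 19 held 3.88% and 4.17% of those called against IgG, and 0.598% and 0.611% of those called against input. RNA Pol II, called against the same 2 control libraries, went the same way, with 6.11% against IgG and 12.5% against input on chromosome 3, and 8.22% and 2.47% on chromosome 19. Across 578 windows of 5 Mb, peak numbers against IgG and against input correlated with Spearman rho = 0.313 in HOXB13 library 1, 0.341 in library 2 and 0.644 for RNA Pol II. With the same control, the HOXB13 libraries correlated with each other at 0.958 for IgG and 0.971 for input.

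**Figure D3:**
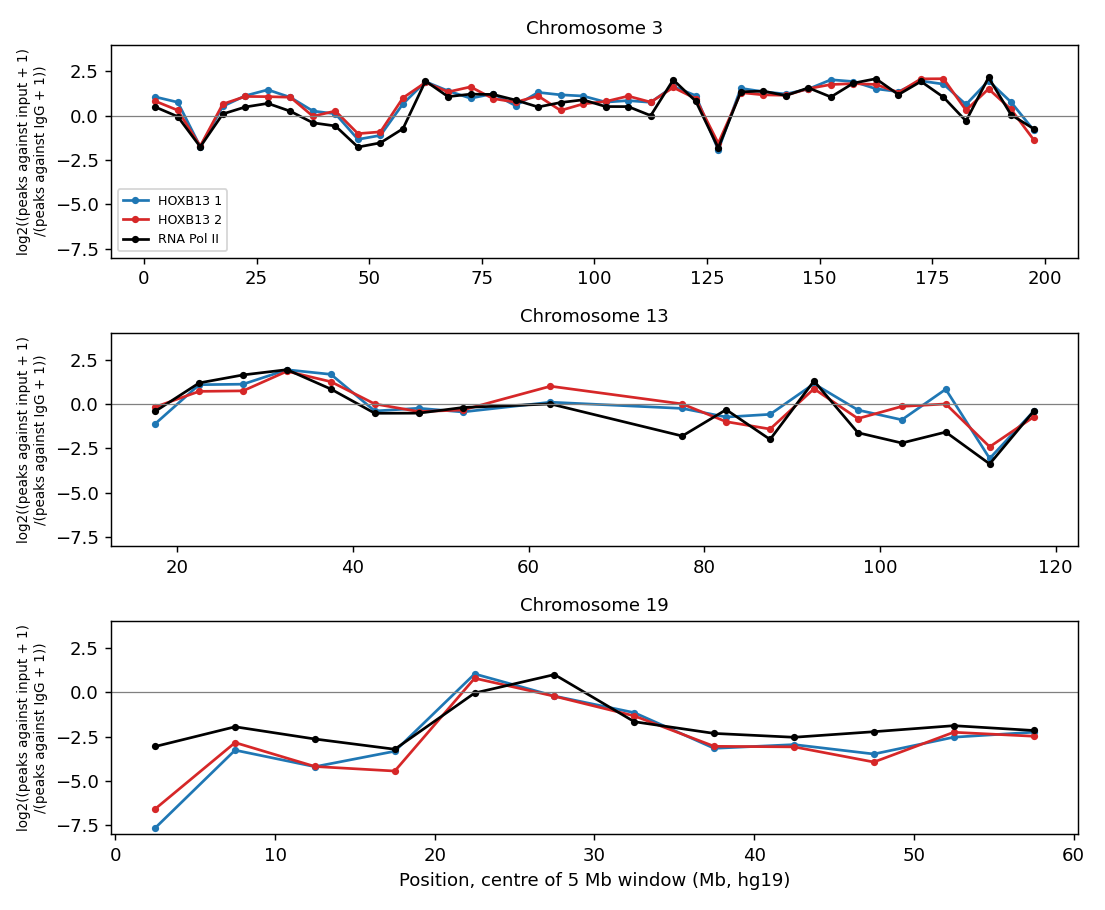
Log2 ratio of the number of peaks called against input to the number called against IgG, each with 1 peak added (y axis), in windows of 5 Mb along chromosomes 3, 13 and 19 (x axis, Mb in hg19). Blue and red points are HOXB13 libraries 1 and 2 and black points are RNA Pol II, joined along the chromosome. The lines of all 3 libraries, which share both controls, take similar courses, mostly above 0 on chromosome 3 and mostly below 0 on chromosome 19.

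The RNA Pol II library gave a comparison of HOXB13 regions with chromatin engaged in transcription. RNA Pol II occupied 9351 regions against both controls, with a median width of 615 bp and the widest spanning 18480 bp. Of the 2731 HOXB13 regions, 278 overlapped an RNA Pol II region, a share of 10.2% (95% Wilson interval 9.10% to 11.4%). Shifted positions gave 0.401% on average and 0.806% at most, so the observed share was 25.4 times chance, and local shifts gave 0.514%, or 19.8 times. Both antibodies were called against the same IgG and input libraries. The shifts break that link too, so these ratios speak to random placement only. A further view from RNA Pol II was that 284 of its 9351 regions, or 3.04% (2.71% to 3.40%), overlapped a HOXB13 region. At 2115 HOXB13 regions, or 77.4% (75.8% to 79.0%), neither RNA Pol II list had a peak. The median distance from a HOXB13 region to the nearest RNA Pol II region was 154 kb, and 244 to 299 kb for shifted positions.

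The share with RNA Pol II differed between controls. With IgG lists alone for both antibodies it was 48.2%, with input lists alone 22.3%, and with peaks of −log10 q of at least 5 it was 5.85%, while circular shifts gave 1.399%, 0.669% and 0.262%. These shares were 34.5, 33.3 and 22.3 times the chance of circular shifts, next to 25.4 for the main share, and 19.3, 18.7 and 18.4 times that of local shifts, next to 19.8. The same 2731 regions overlapped an RNA Pol II peak called against IgG in 15.0% of cases and one called against input in 17.8%. For whole lists, 30.6% and 35.8% of the HOXB13 peaks called against IgG overlapped an RNA Pol II peak called against IgG in libraries 1 and 2, which is 14.9 and 15.6 times the chance of local shifts. With input for both antibodies the shares were 12.6% and 13.8%, or 14.4 and 14.6 times local chance. Without a shared control, 11.2% and 13.4% of the HOXB13 peaks called against IgG overlapped an RNA Pol II peak called against input, 14.6 and 15.8 times local chance. The HOXB13 peaks called against input overlapped an RNA Pol II peak called against IgG in 2.92% and 3.37% of cases, 3.58 and 3.87 times local chance.

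The HOXB13 regions were also ranked into 5 equal groups by their fold. By the fold against IgG, the share with an RNA Pol II peak called against IgG was 9.71% (7.498% to 12.5%) in the lowest group and 27.2% (23.7% to 31.1%) in the highest, with the IgG library shared. With the RNA Pol II list called against input, which shares no control with this ranking, it was 19.2% in both groups (16.1% to 22.7% in each). By the fold against input, the share with an RNA Pol II peak called against IgG was 25.5% (21.98% to 29.3%) in the lowest group and 12.8% (10.3% to 15.9%) in the highest. The share with an RNA Pol II peak called against input was 14.3% (11.6% to 17.5%) and 28.2% (24.5% to 32.1%) in these groups. The share with an RNA Pol II region of both lists was 8.42% (6.38% to 11.1%) in the lowest and 13.7% (11.1% to 16.8%) in the highest group by IgG. By input it was 12.5% (9.94% to 15.5%) and 11.5% (9.11% to 14.5%), intervals that overlap.

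**Figure D4:**
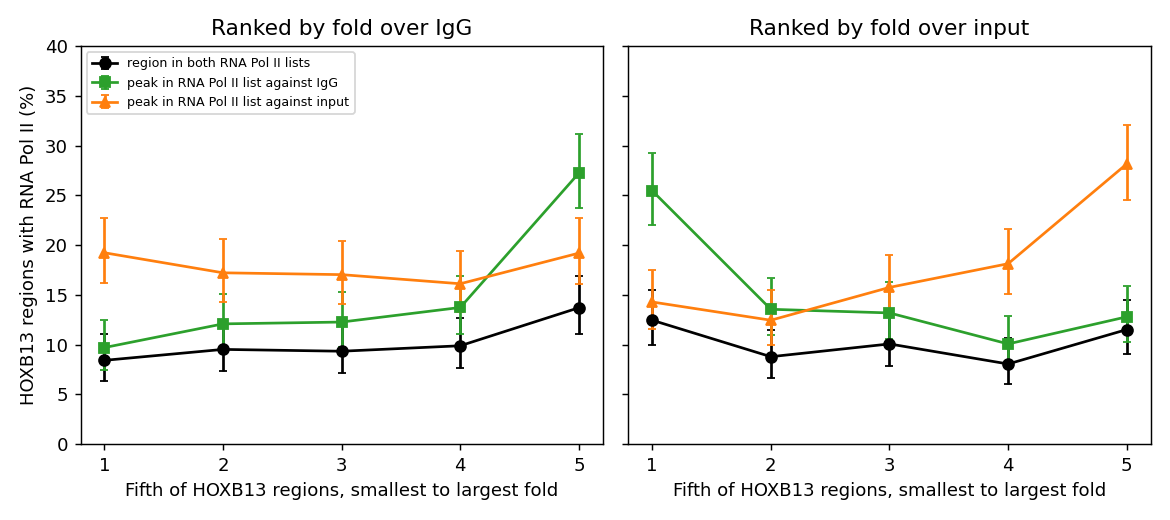
Share of HOXB13 regions with RNA Pol II (%, y axis) in 5 equal groups from the smallest to the largest HOXB13 fold (x axis), ranked by the fold against IgG (left) and input (right). Black circles are RNA Pol II regions of both lists, green squares peaks of the list called against IgG and orange triangles peaks of the list called against input, with 95% Wilson intervals. The green line ends at 27.2% on the left, where the orange line starts and ends at 19.2%, and falls from 25.5% on the right, where the orange line ends at 28.2%.

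The RNA Pol II regions were ranked by the smaller of the folds against IgG and input, a rule chosen after their values were seen. The first lay on chromosome 17 from 56735906 to 56736972, with a fold of 33.6 against IgG and 36.3 against input, and the next on chromosome 11 from 65270345 to 65270961, with 32.3 and 32.0. After these came a region on chromosome 1 from 45196121 to 45197079, with 40.2 and 31.7. Of the first 10 in this order, 2 overlapped a HOXB13 region, namely those on chromosome 17 and chromosome 1 given here. HOXB13 regions, which needed a peak against both controls, had a density of 0.882 per Mb over all chromosomes, with 1.36 on chromosome 3, 1.19 on chromosome 8 and 0.355 on chromosome 19. RNA Pol II regions had 3.02 per Mb over all, with 6.90 on chromosome 19 and 6.33 on chromosome 17. Densities of single lists on chromosome 19 changed with the control. HOXB13 peaks called against IgG were densest there, with 19.6 and 18.0 per Mb in libraries 1 and 2, as were RNA Pol II peaks called against IgG, with 52.4. Against input, HOXB13 peaks had 3.15 and 2.52 per Mb on chromosome 19 and RNA Pol II peaks 10.2. In windows of 5 Mb, peak numbers of HOXB13 and RNA Pol II, both against IgG, correlated with Spearman rho = 0.820 and 0.829, and both against input with 0.623 and 0.649, each with a shared control. Without a shared control, rho was 0.656 and 0.653 for HOXB13 against IgG with RNA Pol II against input, and 0.0425 and 0.0903 for HOXB13 against input with RNA Pol II against IgG.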

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

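The comparisons without a shared control, the regions in at least 3 lists, the single RNA Pol II lists and the named regions against input or without a library were chosen after the data were seen. The number of HOXB13 regions, 2731, was 2654 with summits within 200 bp and otherwise moved by more than 1.5 times: 5057 to 6201 with 1 HOXB13 library left out, 1488 with −log10 q of at least 5, 10471 with IgG lists alone, 8846 with input lists alone and 4640 in at least 3 lists. Most of these follow from asking for fewer or stronger peaks. The share with RNA Pol II, 10.2%, was 6.92% to 7.46% with 1 library left out, 5.85% with the stricter q, 48.2% with IgG lists alone, 22.3% with input lists alone, 15.0% and 17.8% with the RNA Pol II list called against IgG or input, and 9.23% with the summit inside the RNA Pol II region. Each share computed with shifts stayed above the highest shifted value. The shifts do not keep the link through shared controls, and the cause of the differences was not tested here. The share of HOXB13 peaks in the other library against IgG, 38.9% as the mean of both directions, was 39.5% with equal list lengths, 57.9% with the stricter q, 33.6% by summits, 31.3% with reciprocal overlap and 13.5% without a shared control. Against input, 32.6% became 32.8% with equal list lengths, 50.2% with the stricter q, 30.2% by summits, 28.7% with reciprocal overlap and 13.6% without a shared control. The correlation of 0.819 was 0.833 with the stricter q, 0.845 against input, and 0.342 and 0.332 without a shared control. The share of HOXB13 peaks kept with the other control, 20.4% from either list, was 45.5% (from IgG) and 38.0% (from input) with the stricter q, and 18.8% for each with reciprocal overlap. For RNA Pol II, 25.1% from IgG became 29.7%, 24.2% and 14.9% with the stricter q, summits and reciprocal overlap, and 43.1% from input became 71.2%, 37.3% and 23.1%. Of the 10 named regions, 7 had a lower and 3 a higher mean fold against input, and their choice by fold against IgG favours a lower one. None of the 10 moved by more than 1 SD with a library left out, which with 2 libraries holds by construction. The alternatives for promoters, HOX motifs and gene lists were not run, as no hg19 annotation or sequence was used here. No paired analysis was possible because the groups share fewer than 2 replicate numbers. Depth is unknown, so a peak missing from a list is not shown to be absent.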

Other observations

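The tests of the windows of 5 Mb, of the clusters and of the shared IgG library were chosen only after the result was seen. The test of stronger HOXB13 occupancy at RNA Pol II was written before it, but the reading of its bound was changed after the value was seen.

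HOXB13 regions lay close to each other more often than shifted regions did. With regions joined over gaps of up to 12.5 kb, 94 clusters of 2 or more regions held 193 regions, or 7.07% of all. Regions moved singly by 50 to 500 kb gave 49.6 clusters on average and 71 at most. Some clusters, on chromosomes 1 and 2 among others, hold regions separated by gaps shorter than the median region width of 406 bp. Moving regions singly separates such neighbours, and whether they are parts of a single site was not tested. The clusters were not counted without them, so a surplus of separate sites close to each other is not shown. There were 5 clusters of 3 regions, where moved regions gave 1.09 on average and 4 at most. They lay on chromosome 8 from 29172245 to 29178259, chromosome 10 from 29388063 to 29394310, chromosome 11 from 34653169 to 34661534, and chromosome 12 from 54410455 to 54427676 and from 70943398 to 70954809. These clusters were listed after their values were seen.

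Some segments had many more peaks against input than against IgG. All 3 libraries were called against the same input and IgG library, so a regional difference between the controls enters each of them, and their likeness is no independent evidence. On chromosome 13 from 20 to 40 Mb, HOXB13 library 1 had 1050 peaks against input and 383 against IgG, library 2 had 812 and 360, and RNA Pol II had 784 and 253. From 40 to 110 Mb on the same chromosome the numbers were 289 and 311, 228 and 252, and 159 and 246. Against IgG the first of these segments was also denser than the second. In peaks per Mb, HOXB13 library 1 had 19.15 and 4.44, library 2 had 18 and 3.6, and RNA Pol II had 12.65 and 3.51. On chromosome 3 from 150 to 190 Mb, the numbers against input and IgG were 1716 and 513, 1292 and 422, and 1313 and 551. The segments were chosen after the values were seen.

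The proportion of peaks called against input to those called against IgG differed between windows, and the log2 ratio of their numbers correlated between HOXB13 libraries with r = 0.952 and between HOXB13 and RNA Pol II with r = 0.856 and 0.849, with both controls shared by construction. A candidate explanation is that input exceeds IgG in chromatin rich in RNA Pol II. The ratio correlated with the number of strong RNA Pol II regions (−log10 q of at least 20) with rho = −0.437. Where strong was set by the list against input instead of IgG, rho was −0.312. Each count was set by a list called against a control that also enters the ratio, so neither is independent of it. Another candidate is copy number that differs between the input library and the others, although all libraries come from the same cell line. After the RNA Pol II trend was removed, neighbouring windows still correlated at 0.556, which regional base composition could also give and which was not tested. Both explanations stay open, and no value here separates them. No biological explanation was tested, since all libraries come from the same cell line.

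HOXB13 regions scored high against IgG overlapped RNA Pol II peaks called against IgG more often, and the IgG library that both use may account for part of it. From the lowest to the highest of the 5 groups by fold against IgG, the share rose by 17.5 percentage points (95% Newcombe interval 13.0 to 21.997) with the RNA Pol II list called against IgG and changed by −0.0352 (−4.71 to 4.64) with the list called against input, a difference of 17.6 points (bootstrap interval 13.2 to 21.8) that restates the pattern. The rule set for this explanation also asked that the share with the list called against IgG stay level by fold against input. That share fell instead by 12.7 points (interval of the change −17.2 to −8.03). Regions had to hold peaks against both controls, and a library's folds against IgG and input correlate. A level share therefore need not follow from a shared IgG library, so the fall does not decide the matter. By fold against input, the share with the list called against input rose by 13.9 points (9.06 to 18.6). With single RNA Pol II lists, the share thus rose only where list and ranking shared a control. The explanation by the shared IgG library stays open. Stronger HOXB13 occupancy at RNA Pol II also stays open: with RNA Pol II regions of both lists the change was 5.29 points (1.57 to 9.03) by fold against IgG and −0.937 (−4.81 to 2.93) by fold against input, where the highest group had 11.5%, and these lists share a control with either ranking. The bound set beforehand against it, a share that is not higher or intervals that overlap, was met. The first part was met by less than its spread. The second was badly chosen, because overlapping intervals leave a rise of up to 2.93 points possible. Under the bound as first written the result counts against this explanation, and it was read as open only after the value was seen.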
